A study of Arabidopsis thaliana with 18 samples.

How the data were processed

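Small RNAs were measured in HA-tagged AGO1, HA-tagged AGO2 and untagged Col-0 plants of Arabidopsis thaliana carrying Cuscuta campestris, as a pull-down and its input from each lysate. Per the labels' protocols, 3-day-old seedlings of the parasite were placed on host inflorescence stems at least 15 cm long, with 10 attachments per plant. The stem beneath the haustoria was taken after 10 days and about 400 segments were pooled per replicate. Tagged protein was recovered with magnetic beads against HA. Libraries were made with a low-bias small RNA kit, size-selected together in a pool, and sequenced single-end. The 18 samples fell into 6 groups of 3 by their labels, and replicates were numbered 2, 3 and 4. The labels do not say how the pools of one line were kept apart, so p-values measure only the spread between these pools, part of which may be technical.

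One table per pull-down was deposited, with 52573 features in each. Per the file headers, each feature had a log2 ratio and a log10 abundance, and each microRNA its length. The deposited log2 values behaved as the ratio of RPM in 2 fractions, with 0.5 read in place of 0 reads, and were given only where the RPM of at least 1 fraction was 2 or more. The deposited log10 values behaved as log10 of 1 plus the mean RPM of both fractions. These readings come from the values, since the headers name the columns and no more. In each of the 9 tables, 100% of the ratios resolved into whole reads of both fractions, within 0.02 read and 0.001 on the log2 scale. Library totals and reads per feature followed from this. That the pull-down is the numerator is an assumption. TAIR10 is named in the submitters' processing notes, and siRNA loci carried C. campestris chromosome names. The adapter trimmer, aligner, counter, locus caller and the C. campestris assembly are not given in the sources used here. How reads shared by near-identical microRNAs were split is not given either, so members of one family with similar sequences are uncertain.

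Totals were 2602128 to 24461097 reads for pull-downs and 1659705 to 4099067 for inputs. The floor of 3 reads that stood for lines without reads was worth 0.123 to 1.15 RPM in the pull-downs. Reads came without molecular identifiers, so intervals on reads cover counting error only; they are exact 95% intervals for the ratio of counts given library totals. Ratios to a line with 1 to 3 reads are given with that interval.

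Features were tested where each line had a ratio in at least 2 of its 3 libraries and at least 10 pull-down reads in at least 3 libraries. This left 869 features, 149 microRNAs and 720 siRNA loci, of which 453 had a ratio in all 9 libraries. The deposited log2 ratios of the 9 pull-downs were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per line, without a replicate block, with the spread moderated along mean abundance (prior degrees of freedom 11.2) and Benjamini-Hochberg adjusted p under 0.05. Tests asked whether each line's mean differed from 0 and whether lines differed in pairs. The design fixed before the data were examined had a count model, with limma on log2(value + 1) as its fallback. The ratio in the files replaced both, because pull-down and input stand in 1 value, and the fallback was run as an alternative. The filter on ratios and reads was set once the unit of the files was known. As it counts pull-down reads, it favours features that are high in a pull-down, and siRNA loci had most pull-down reads with AGO2. The share of tested loci called is therefore not that of all loci. Lists were tested on features that passed the same filter, so their p-values for loci carry this limit too. The scaling was by library total, as the ratios were deposited, since a pull-down can change most features. Median centring, an alternative below, subtracts each library's median over the tested features, of which 720 of 869 were siRNA loci. It thus removes most of the loci's own shift and moves microRNAs by the same amount.

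Lists of small RNAs, the rule for naming and the alternatives were also among the choices fixed then. In each comparison between lines, features were named if they were called, had a mean of at least 10 RPM and did not overlap between lines. The 8 largest and 8 lowest of them were taken, and from each list up to 4 of the most abundant members, or all members for lists of 8 or fewer. Of 18 lists, 9 had members in the files: conserved, Brassicaceae, trigger, nutrient stress and C. campestris (interface-induced) microRNAs, 5' U and 5' A microRNAs, 24-nt RNAs, and siRNA loci. Trans-acting siRNA loci, host targets of parasite microRNAs, 3 classes of host phased siRNA loci, microRNA star strands, transposable elements, structural RNAs and organelle genomes were not analysed here. Lists were tested with camera over features with ratios in all 9 libraries, with a preset correlation of 0.01 and with an estimated one. Library composition was compared by exact two-sided permutation tests, with Benjamini-Hochberg adjustment over 90 shares and, for ratios of summed classes, over 54 tests.

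The replicate numbers were checked by the correlation, across 136 microRNAs, of deviations from the line means. Same-numbered AGO2 and Col-0 libraries correlated at 0.13, 0.11 and 0.11, so that a fit with these numbers as a block is given beside the main one. Values this low, across microRNAs that are not independent, do not establish pairing. With the block limma called 524 higher and 5 lower with AGO2 beyond Col-0, against 531 and 4. Same-numbered libraries of the other lines correlated at 0.37, 0.38 and -0.04 (AGO1 and Col-0) and 0.14, -0.05 and -0.08 (AGO1 and AGO2). Whether the numbers pair any lines was thus not settled.

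Alternatives were median centring, no filter on reads, a mean of at least 10 RPM, pseudocounts of 0.1 and 10 RPM, pull-downs without inputs, a replicate block, each library left out, the share of distinct features, and an estimated correlation for lists. After the data were seen, the fallback on log2(RPM + 1), reads thinned to 2602128 per pull-down and 1659705 per input, lines without reads set at 3 reads, microRNAs fitted alone and microRNAs as the only background for lists were added, as was a test of depth on the 124 loci with at least 10 thinned reads in each of the 9 inputs, and a count over the splits that part all same-numbered pairs of AGO2 and Col-0. On simulated data made from the 869 features for AGO1 beyond Col-0, limma called 54% of 50 changes of log2 size 5, 18% of size 3 and 2% of size 2. Of the 39, 24 and 20 with enough simulated reads to be tested it called 69.2%, 37.5% and 5%, and 0.8% of the 248 unchanged features tested. For AGO2 beyond Col-0 it called 52%, 10% and 6%, which is 65%, 17.2% and 13.6% of the 40, 29 and 22 tested, and 0% of the 227 unchanged features tested. For changes of log2 size 1 it called 0% in both. All lines were simulated around the Col-0 ratios, the lowest of them raised, with 669 of the 869 features unchanged. Values were decoded and tabulated with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Features without a ratio in enough libraries were left out of the tests. No gene annotation of C. campestris was used here.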

Results

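Small RNAs bound by tagged ARGONAUTE proteins were sequenced from Arabidopsis thaliana inflorescence stems beneath the haustoria of the parasitic plant Cuscuta campestris (dodder). The haustorium is the feeding organ through which the parasite is joined to the host. Plants carried HA-tagged AGO1 in the ago1-36 mutant, HA-tagged AGO2 in the ago2-1 mutant, or no tag (Col-0). ARGONAUTE proteins hold small RNAs and use them to find target transcripts. In A. thaliana AGO1 is known to hold mainly small RNAs that start with U, and AGO2 mainly those that start with A. Pull-downs with anti-HA beads and inputs from the same lysates gave 18 samples in 6 groups of 3, numbered as replicates 2, 3 and 4. Each replicate pooled about 400 stem segments taken 10 days after attachment. Pull-down libraries held 14473000, 9176436 and 2989148 reads for AGO1, 2602128, 4492610 and 4141981 for AGO2, and 24461097, 5764446 and 3889235 for Col-0, as worked out from the deposited values. Input libraries held between 1659705 and 4099067 reads.

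The files listed 52573 features. There were 136 C. campestris microRNAs induced at the interface, 73 A. thaliana microRNAs, and 59 canonical microRNAs of either or both species. The other 52305 were C. campestris siRNA loci, of which 242 were 21-nt, 1701 were 22-nt and 50362 were 24-nt loci. Listed features took 2.61% to 4.45% of the reads of the AGO1 pull-downs, 6.45% to 15.2% of those with AGO2, and 0.330% to 0.881% of those from Col-0. They took 14.2% to 22.2% of the input reads. What the remaining reads were is not analysed here, and every ratio was taken over all reads of a library, in reads per 1e6 reads (RPM). The pull-down was taken as the numerator of the deposited log2 ratio, an assumption that the files do not state, and pull-down and input would change places throughout if it were the denominator. The numerator fraction held 0.330% to 0.881% listed reads in Col-0 and 6.45% to 15.2% with AGO2, whereas the denominator held 14.2% to 22.2% across the lines. The reverse would need inputs that differ by tag and pull-downs that do not, which argues against it. In all, 149 microRNAs and 720 siRNA loci had enough reads to be tested.

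MicroRNA reads in the AGO1 pull-down started almost entirely with U, at 95.3% ± 0.546 (SD, n = 3), against 40.9% ± 1.17 in its input. The AGO2 pull-down was led by 5' A microRNAs, at 60.2% ± 7.36 against 21.6% ± 3.10 in its input, and 5' U microRNAs made up 23.1% ± 8.91. The highest of these 5' U shares, 33.3%, was that of AGO2 replicate 2, whose input share of 41.9% was the lowest of the AGO2 inputs. MicroRNAs starting with G made up 15.9% ± 2.81 of microRNA reads with AGO2 and 1.18% ± 0.322 with AGO1, against 16.8% ± 6.84 and 36.7% ± 9.96 in their inputs. The microRNA reads of the untagged pull-down also started mostly with U, at 88.1% ± 4.24 against 49.0% ± 9.92 in its input. There were 45321 ± 58548 microRNA reads per untagged library, against 227644 ± 94884 with AGO1. By length, 22-nt microRNAs led with AGO1 at 51.5% ± 3.07, against 35.2% ± 10.3 in its input, where 21-nt microRNAs led at 61.2% ± 10.8. These shares weigh microRNAs by their reads. The 21-nt ccm-miR12490defgh alone had 14036 RPM over the 9 inputs and a log2 ratio of -10.97 with AGO1. The shares alone thus do not show a preference for length. With AGO2, 21-nt microRNAs led at 79.2% ± 4.95, against 41.7% ± 6.95 in its input, where 22-nt microRNAs led at 52.7% ± 5.92. Interface-induced C. campestris microRNAs took 53.1% ± 6.25 of the listed reads with AGO1 (27.2% ± 1.38 in its input) and 39.6% ± 5.22 with AGO2 (36.1% ± 2.81 in its input). The order of AGO1 and AGO2 in the 5' U, 5' G, length and interface-induced shares would turn if the inputs were the pull-downs, with 5' U at 46.6% ± 4.29 in the AGO2 input. That in the 5' A share would not (12.8% ± 5.10 in the AGO1 input). The 3 values of one line lay wholly apart from the 3 of the other for the 5' U, 5' A, 5' G, 21-nt and 22-nt shares of AGO1 and AGO2. In a two-sided exact permutation test, 3 libraries against 3 cannot give a p below 0.1, which is adjusted p = 0.12 over the 90 shares compared, so none passed a threshold of 0.05.

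**Figure D1:**
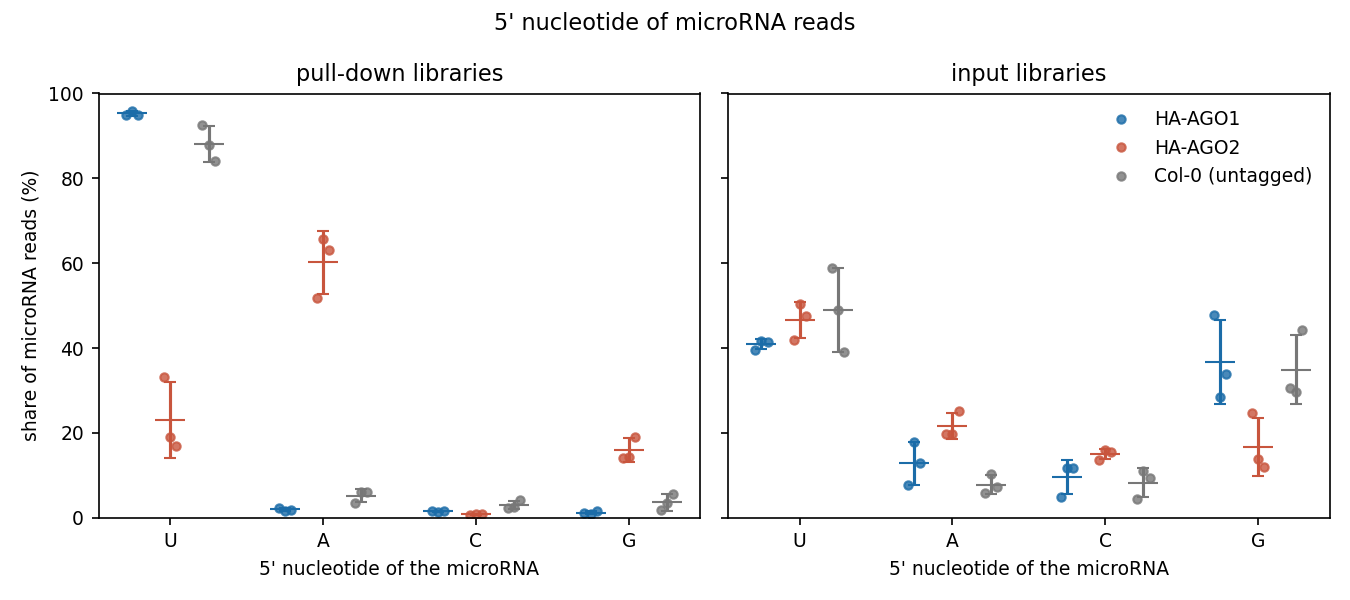
Share of microRNA reads (percent, y axis) by 5' nucleotide (x axis) in the pull-downs and inputs of the AGO1, AGO2 and Col-0 lines; points are libraries, bars are means and error bars are SD (n = 3). In the pull-downs 5' U holds 95.3% with AGO1, 23.1% with AGO2 and 88.1% in Col-0.

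The untagged Col-0 pull-down measured what the beads recover without a tag. Nearly every tested small RNA was depleted relative to input. Summed over all 5' U microRNAs, the log2 ratio was -3.49 ± 1.16 (SD, n = 3), over 5' A microRNAs -4.95 ± 1.29, and over 24-nt loci -5.29 ± 0.75. Of 149 tested microRNAs 133 fell and 0 rose in limma (0 also at an unadjusted p under 0.05). The highest ratio among the named microRNAs was that of ath-miR398bc, a microRNA known to act on copper superoxide dismutase transcripts, at 0.53 ± 0.18 (adjusted p = 0.458). Over all features, limma called 12 higher and 779 lower of 869. After each library was centred on the median of its tested features, 47 were higher and 6 lower.

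With AGO1, 16 of 149 tested microRNAs rose above their own input, and 623 of 720 siRNA loci fell below it. The leading named examples were ath-miR398bc, at a log2 ratio of 5.11 ± 1.33 (SD, n = 3, adjusted p = 3.69e-05), and ath-miR393ab, known to act on auxin receptor transcripts, at 3.82 ± 0.42 (adjusted p = 0.000376). Others were ath-miR398a-3p at 2.96 ± 0.81, ath-miR161.2 at 2.49 ± 1.76 and ath-miR158a-3p at 1.78 ± 0.56. Of 104 tested 5' U microRNAs 13 were higher and 17 lower, and of 20 5' A microRNAs 17 were lower. Without AGO1 replicates 2, 3 and 4 the 16 higher microRNAs became 6, 10 and 8, and the 13 starting with U became 6, 9 and 6. The 17 lower ones starting with U became 8 and 11 without replicates 2 and 3. As whole classes, 5' U microRNAs stood at 0.26 ± 0.34 and 24-nt loci at -4.85 ± 0.74. Over all features 27 were higher and 672 lower, with 13 and 16 higher without AGO1 replicates 2 and 3. After median centring the split became 130 higher and 29 lower, with 101 higher and 11 lower among microRNAs and 29 higher and 18 lower among loci.

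With AGO2, 10 of 20 microRNAs starting with A rose above their input, and 65 of 104 starting with U fell below it. The C. campestris microRNA ccm-IIM-93 stood at 6.20 ± 0.32 (SD, n = 3, adjusted p = 0.00042). The A. thaliana ath-miR408-3p, known to act on transcripts of copper proteins, stood at 4.54 ± 1.04 (adjusted p = 0.000165), and ath-miR837-3p at 4.00 ± 1.10. The 5' G microRNA ccm-IIM-27 stood at 2.96 ± 0.19 and the 5' U microRNA ath-miR159b-3p, of a family acting on MYB transcripts, at 2.25 ± 0.99. Of 16 5' C microRNAs 12 were lower. Of 720 siRNA loci 4 were higher and 9 lower. Summed siRNA loci stood at 1.04 ± 0.98 for 21-nt and 0.48 ± 0.51 for 22-nt loci, while 24-nt loci lay below their input in each library, at -1.41 ± 0.30. Without AGO2 replicates 3 and 4 the 15 higher microRNAs became 8 and 9, and the 10 starting with A became 5 and 6. Over all features 19 were higher and 90 lower (9 and 11 higher without AGO2 replicates 3 and 4), and 34 higher and 81 lower after median centring.

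**Figure D2:**
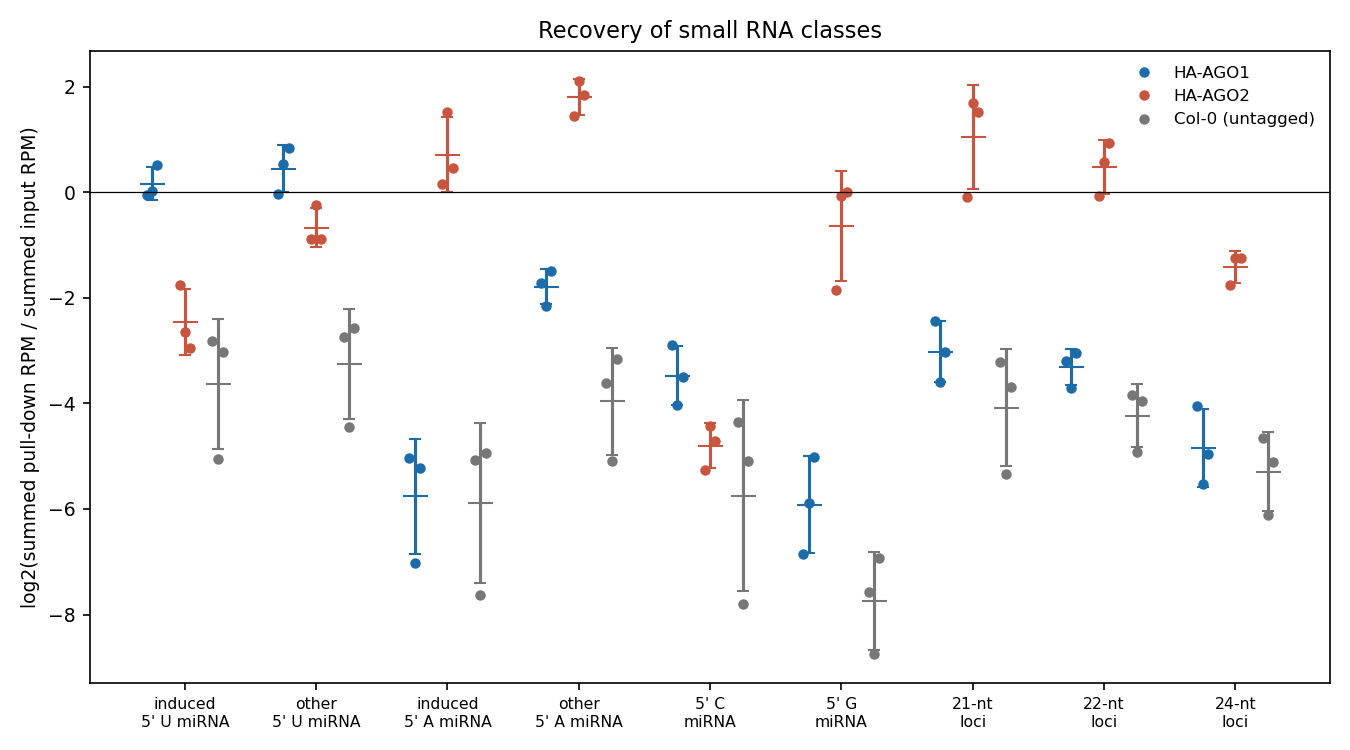
Log2 ratio of pull-down over input (y axis) of reads summed over each class of small RNA (x axis), by line; points are libraries and bars show the mean and SD (n = 3). Induced microRNAs are the interface-induced ones of C. campestris, and other ones those of A. thaliana and canonical ones of either species. Classes of siRNA loci lie between -1.41 and 1.04 with AGO2 and between -5.29 and -3.02 in the AGO1 and Col-0 lines, whereas 5' U microRNAs lie at 0.17 (induced) and 0.44 (other) with AGO1.

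Which small RNAs AGO1 held beyond the untagged background was asked by comparing the ratio over input in the AGO1 line with that in Col-0. Of the 5' U microRNAs, 20 of 62 interface-induced ones of the parasite, 6 of 15 of the host and 9 of 27 canonical ones of either species were higher with AGO1. Among host microRNAs the largest difference was that of ath-miR828 (below), followed by ath-miR824-5p at 5.19 ± 1.32 (SE, log2, adjusted p = 0.0466), ath-miR395ade at 5.06 ± 1.00 (adjusted p = 0.0269) and ath-miR395bcf at 4.89 ± 0.95. The miR395 family, known to act on sulfate assimilation, starts with C. Both of its sequences lay below their own input in each AGO1 library. The log2 ratios were -2.41, -1.31 and -0.75 for ath-miR395ade, and -0.82, -0.78 and -0.95 for ath-miR395bcf. Their differences thus rest on still lower ratios in Col-0. Both miR398 sequences rose, ath-miR398a-3p by 4.72 ± 1.22 and ath-miR398bc by 4.58 ± 0.98, and ath-miR161.2, known to act on pentatricopeptide repeat transcripts, by 4.60 ± 1.18. Among C. campestris microRNAs, ccm-IIM-23b rose by 5.80 ± 1.39, ccm-IIM-43a by 4.81 ± 1.09 and the abundant ccm-miR12496 by 4.39 ± 1.00. The rule names ccm-miR12495ac only in the comparison of AGO2 with AGO1. It had 4.00 ± 1.04 here, and its fits without single libraries are not given for this comparison.

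The smallest differences among the called features that met the rule for naming included those of well-known families. They ran from 3.28 ± 0.89 for ccm-miR12465d and 3.34 ± 0.92 for ccm-miR164c, of a family acting on NAC transcripts, to 3.50 ± 0.95 for the shared miR166, which acts on HD-ZIP III transcripts. Between them lay the shared miR159a at 3.40 ± 0.94, ath-miR394ab at 3.41 ± 0.93, the shared miR319, acting on TCP transcripts, at 3.42 ± 0.89, ccm-miR12482b at 3.47 ± 0.89 and ccm-IIM-76a at 3.48 ± 0.96. The 5' A microRNA ccm-miR12482b was the 1 called of 20 of its kind, and it lay below its own input in each AGO1 library (-0.98, -1.56 and -0.57). The A. thaliana microRNA ath-miR828, known to act on MYB transcripts, rose by 10.08 ± 1.71 (adjusted p = 0.0184), with 401 pull-down reads in AGO1 and 8 in Col-0. Of the siRNA loci 2 of 720 were called, both named after their values were seen. They were the 24-nt loci Cluster_52600 (chromosome 23, 1047019 to 1047563) at 7.96 ± 1.89 and Cluster_61836 (chromosome 27, 10519712 to 10520617) at 8.19 ± 2.22. Each kept its call in only 1 of the 6 fits that left out a library. Each also lay below its input in 1 AGO1 library, at -3.62 in replicate 2 and -4.41 in replicate 4. No 21-nt or 22-nt locus was called by limma (0 of 23 and 0 of 117), with 5 and 12 higher at an unadjusted p under 0.05.

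By group, 35 of 104 5' U microRNAs rose over all features tested, and 90 when adjusted over the list alone, with a median difference of 3.57. The camera test of this list against the other features gave adjusted p = 9.52e-29 with a preset correlation and adjusted p = 0.0813 with an estimated correlation. The 20 5' A microRNAs had a median of -0.03, with 1 higher over all features and 1 adjusted over the list alone (adjusted p = 0.0207, lower than other features, and adjusted p = 0.352 with an estimated correlation). Of 98 C. campestris microRNAs 21 rose, and 57 adjusted over the list alone (adjusted p = 0.215 with an estimated correlation, and lower at adjusted p = 0.257 with microRNAs as the only background). The 57 became 35 without AGO1 replicate 4 or Col-0 replicate 3. Of 38 conserved microRNAs 13 rose, and 32 adjusted over the list alone. Of 11 Brassicaceae microRNAs 4 rose (9 adjusted over the list alone), ath-miR824-5p, ath-miR161.2, ath-miR828 and ath-miR158a-3p, the last by 3.98 ± 1.06, while ath-miR161.1 at 3.44 ± 0.99 and ath-miR173-5p at 3.42 ± 1.06 did not pass. Of 7 nutrient stress microRNAs 4 rose (6 adjusted over the list alone), those of miR395 and miR398 named above, and ath-miR408-3p had 0.04 ± 0.99. Each of these 3 lists had adjusted p = 0.149 with an estimated correlation. Of 5 microRNAs that trigger secondary siRNAs 1 rose, ath-miR828, and 5 adjusted over the list alone (adjusted p = 0.211 with an estimated correlation). The others were ccm-miR393a at 3.82 ± 1.14, ath-miR393ab at 3.70 ± 1.05, ath-miR173-5p and ath-miR472-3p at 3.12 ± 1.23. The list of 24-nt RNAs, 580 loci and 5 microRNAs, had 4 of 585 members higher and 0 adjusted over the list alone in limma, with a median of 0.30 that turned to -0.55 after centring. The 4 were both loci above, ccm-IIM-17 at 3.84 ± 0.99 and ccm-IIM-12b, named after its value was seen, at 4.48 ± 1.21. As a list they were lower than other features with either correlation (adjusted p = 0.0184 with an estimated correlation). All 720 loci had a median of 0.52, which turned to -0.27 after centring, with 2 higher over all features, 0 adjusted over the list alone, and adjusted p = 0.0184 with an estimated correlation.

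Over all features, limma called 40 higher with AGO1 and 0 lower, with 134 higher and 6 lower at an unadjusted p under 0.05, and in 235 of 869 features (27.0%, against 16.5% by chance with the ratios present) the lines did not overlap. Of the 486 with all 6 ratios the share was 29.2%, against 10% by chance. Leaving out single libraries ended most calls, with 5, 0 and 2 left without AGO1 replicates 2, 3 and 4, and 1, 0 and 1 without Col-0 replicates 2, 3 and 4; where none was left, 146 and 123 features had an unadjusted p under 0.05. Adjusted over the list alone, 84, 79 and 75 of 104 5' U microRNAs stayed higher without AGO1 replicates 2, 3 and 4, and 87, 73 and 88 without Col-0 replicates 2, 3 and 4, with medians of 2.94 to 3.96. Each of the 21 features that the rule names and limma called here, and each of the 3 named after their values were seen, lost its call in at least 1 of these 6 fits. The differences of the 21 stayed above 0 in every fit, the lowest being 2.57 for the shared miR159a. Median centring, which lowered the median difference of the tested features by 0.76 here, left 0 higher and 0 lower in limma (121 at an unadjusted p under 0.05), although 71 of 104 5' U microRNAs were still higher when adjusted over the list alone.

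What AGO2 held beyond the untagged background was asked in the same way. Of 20 microRNAs starting with A 18 rose with AGO2, as did 493 of 720 siRNA loci of the parasite and 10 of 104 microRNAs starting with U. Against their own AGO2 input only 4 of the 720 loci were higher, and 9 were lower. The rise of the loci is thus relative to the stronger depletion in Col-0. The filter on pull-down reads favoured loci recovered with AGO2, and counts without it and after centring are given below. The largest difference was that of the host microRNA ath-miR837-3p (AAACGAACAAAAAACTGATGG) at 11.54 ± 1.11 (SE, log2, adjusted p = 6.34e-06), with 2062 pull-down reads in AGO2 and 1 in Col-0, a ratio of 6260 per read sequenced (95% exact interval 1122 to 247385). The host ath-miR408-3p (ATGCACTGCCTCTTCCCTGGC) rose by 7.89 ± 0.99. Among C. campestris 5' A microRNAs, ccm-IIM-93 (AGAAGCTACTAAAAACTTCACA) rose by 9.21 ± 1.49, ccm-IIM-26 by 9.09 ± 1.17, ccm-miR12469bc by 8.60 ± 1.01, ccm-IIM-79a by 8.51 ± 1.20 and ccm-IIM-56 (AGGATGGATGGACTTTGTGAG) by 8.36 ± 0.92. The last of these stood at 10957 ± 6656 RPM in the AGO2 pull-down, 16.5 ± 4.49 with AGO1 and 14.7 ± 9.09 in Col-0 (SD, n = 3). The 5' G microRNA ccm-miR12469a rose by 8.53 ± 1.22, and ccm-IIM-27, also 5' G, by 7.50 ± 0.83.

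Of the siRNA loci, 20 of 23 21-nt, 105 of 117 22-nt and 368 of 580 24-nt loci were higher. After median centring 0, 3 and 3 were, and without Col-0 replicate 3 the 368 became 244. The 21-nt locus Cluster_42541 (chromosome 18, 3132005 to 3133306) rose by 8.48 ± 1.45 and Cluster_23950 (chromosome 10, 193116 to 193834) by 5.40 ± 0.98. The 22-nt loci Cluster_49936 (chromosome 21, 9389226 to 9391797) and Cluster_49941 (chromosome 21, 9398870 to 9401272) rose by 6.38 ± 1.01 and 5.98 ± 0.89. The 24-nt locus Cluster_28818 (chromosome 11, 16144834 to 16145606) was called at 9.89 ± 1.88, with 234 reads against 1 in Col-0, a ratio of 710 (95% exact interval 126 to 28179). Coordinates are those of the C. campestris assembly of the files, whose name and gene annotation are not given in the sources used here.

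By group, 18 of 20 5' A microRNAs rose over all features and 18 adjusted over the list alone (10 higher and 1 lower after centring, and 12 and 1 adjusted over the list alone), with a median of 7.47 (2.96 after centring) and adjusted p = 0.225 with an estimated correlation. All 720 loci had 493 higher and 3 lower (500 and 3 adjusted over the list alone; 6 and 19 over all features after centring; 1 lower without AGO2 replicate 3 or Col-0 replicate 3), a median of 5.05 (0.56 after centring) and adjusted p = 0.0449 with an estimated correlation. The list test used only loci that passed the filter on pull-down reads, which favours loci recovered with AGO2, so its p does not speak for all loci. Without this filter 2598 of 17568 loci were higher and 11 lower. Of all ratios given, 57.2% to 89.6% per Col-0 library and 23.2% to 48.2% per AGO2 library rested on 0 pull-down reads set at 0.5 read. Such ratios depend on depth, so the unfiltered count is not free of bias either. The list of 24-nt RNAs had 368 higher and 3 lower (371 and 3 adjusted over the list alone, the 371 becoming 240 without Col-0 replicate 3, and 5 and 1 lower without AGO2 replicates 2 and 3), a median of 4.66 (0.16 after centring) and adjusted p = 0.284 with an estimated correlation. Of 104 5' U microRNAs 10 rose, and 6 adjusted over the list alone, with a median of 0.33 that turned to -4.18 after centring (adjusted p = 0.134 with an estimated correlation). After centring 0 were higher and 71 lower (1 and 85 adjusted over the list alone). Relative to the other features this list was lower although its median was above 0. The same held for the conserved, Brassicaceae, trigger and C. campestris microRNA lists, whose medians of 0.35, 0.63, 0.34 and 0.86 turned to -4.16, -3.87, -4.16 and -3.64 after centring (adjusted p = 0.225 with an estimated correlation for each). After centring the first 3 had 1, 0 and 0 higher and 25, 5 and 3 lower. With microRNAs as the only background the first 3 had adjusted p = 0.733, 0.555 and 0.555, and C. campestris microRNAs turned to higher (adjusted p = 0.695). Of 38 conserved microRNAs 9 rose (9 adjusted over the list alone), including the shared miR172cd, which acts on APETALA2-like transcripts, by 5.78 ± 0.88 and ath-miR159b-3p by 5.33 ± 0.94. The shared miR159a rose by 4.16 ± 0.94, a difference that turned to -0.34 after centring. Of 98 C. campestris microRNAs 26 rose and 1 fell (22 and 1 adjusted over the list alone), and 10 were higher and 52 lower after centring. The 1 lower became 4 and 5 without AGO2 replicate 2 and Col-0 replicate 3, and 0 without AGO2 replicate 3 or Col-0 replicate 4 in limma, where ccm-IIM-87 kept its sign. Of 11 Brassicaceae microRNAs 2 rose (2 adjusted over the list alone), ath-miR161.2 by 3.77 ± 1.18, turning to -0.73 after centring, and ath-miR828 by 7.85 ± 1.71, which was also the 1 of 5 trigger microRNAs that rose (1 adjusted over the list alone). Of 7 nutrient stress microRNAs 3 rose (3 adjusted over the list alone), ath-miR408-3p, ath-miR395ade by 3.91 ± 1.00 and ath-miR395bcf by 3.74 ± 0.95. The latter pair turned to -0.60 and -0.76 after centring, and both lay below their own input in each AGO2 library. The list's median of 0.92 turned to -3.58, with 1 higher and 3 lower after centring, and the list was not called (adjusted p = 0.298, and adjusted p = 0.561 with an estimated correlation). Without Col-0 replicate 3 ath-miR161.2 had 2.56 and lost its call.

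Of the 4 features that fell with AGO2, 2 were named after their values were seen, the 24-nt loci Cluster_28731 (chromosome 11, 15726265 to 15726688) at -4.56 ± 1.71 and Cluster_38614 (chromosome 16, 5116411 to 5116815) at -4.21 ± 1.62. The other 2 were the 24-nt locus Cluster_18222 (chromosome 7, 5599342 to 5600189) at -6.07 ± 2.11 and the 5' C microRNA ccm-IIM-87 at -3.93 ± 1.28. Cluster_28731 lost its call without AGO2 replicate 3 (-4.00) or 4 (-3.89) or Col-0 replicate 2 (-3.08), and Cluster_38614 in 4 of the 6 fits that left out a library. Cluster_18222 lost its call without Col-0 replicate 3 (-3.57), and ccm-IIM-87 without AGO2 replicate 3 (-2.81) or Col-0 replicate 4 (-3.24). The smallest rises among features that met the rule for naming all turned below 0 after centring, those of ccm-IIM-3 (2.74 ± 1.11 to -1.76), ccm-miR12465d (2.81 ± 0.89 to -1.70), ccm-IIM-34a (2.95 ± 1.09 to -1.55), and the 24-nt loci Cluster_23044 (3.27 ± 1.23 to -1.23), Cluster_38407 (3.28 ± 1.37 to -1.22) and Cluster_41871 (3.58 ± 1.41 to -0.92). With the replicate number as a block, Cluster_38407 lost its call (adjusted p = 0.054). Leaving out AGO2 replicate 3 gave ccm-miR12465d 2.57 and ended its call, and the other 5 lost theirs in 3 to 5 of the 6 fits that each left out a library.

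Over all features, 531 were higher and 4 lower with AGO2 in limma, and in 68.0% of features (against 14.3% by chance with the ratios present) the lines did not overlap (66.3% of the 555 with all 6 ratios, against 10% by chance). Median centring lowered the median difference by 4.50, and gave 18 higher and 102 lower. The 4 lower became 8 without AGO2 replicate 2, 6 without Col-0 replicate 3 and 1 without AGO2 replicate 3.

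The direct comparison of AGO2 with AGO1 asked which small RNAs each protein held more of. MicroRNAs separated by their first nucleotide: 17 of 20 5' A microRNAs were higher with AGO2, and 68 of 104 5' U microRNAs were higher with AGO1. Among microRNAs the largest differences toward AGO2 were those of ath-miR837-3p at 11.40 ± 1.11 (SE, log2, adjusted p = 7.68e-06), ccm-IIM-93 at 10.25 ± 1.49, ccm-IIM-79a at 9.03 ± 1.20, ccm-IIM-56 at 8.82 ± 0.92, ccm-miR12474b (AGTGGATGGCAAGAAGTGAGC) at 8.80 ± 1.09, ccm-IIM-29 at 8.31 ± 0.93, ccm-IIM-26 at 8.19 ± 1.17 and ccm-miR12478a at 8.15 ± 1.20, all 5' A. Among microRNAs that met the rule for naming, those toward AGO1 were the shared miR171, which acts on SCARECROW-like transcripts, at -7.00 ± 1.34 (adjusted p = 0.00179), ath-miR398a-3p at -6.33 ± 1.22, ath-miR163 at -5.30 ± 1.16 (adjusted p = 0.00285), ccm-miR12496 (TGCATCTCCGCCTCCTGAGCAC) at -5.21 ± 1.00, ccm-miR12495ac (TACTCAGGCGCGGCGTAGCCAT) at -5.04 ± 1.04, and the 5' C microRNAs ccm-IIM-87 at -5.10 ± 1.28 and ccm-IIM-48a at -5.04 ± 1.21. The third of the 5' C microRNAs that were lower, ccm-IIM-95, had -4.50 ± 1.53, was named after its value was seen, and lost its call without AGO1 replicate 3 (-3.73) or AGO2 replicate 3 (-2.74). For ath-miR163 the call rested on 129 pull-down reads with AGO1 against 1 with AGO2, a ratio of 54.4 (95% exact interval 9.59 to 2166). The only 5' U microRNA called toward AGO2 was ccm-miR12481 (TATGTAGCAATTTTGAAGAAT) at 5.96 ± 1.11.

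**Figure D3:**
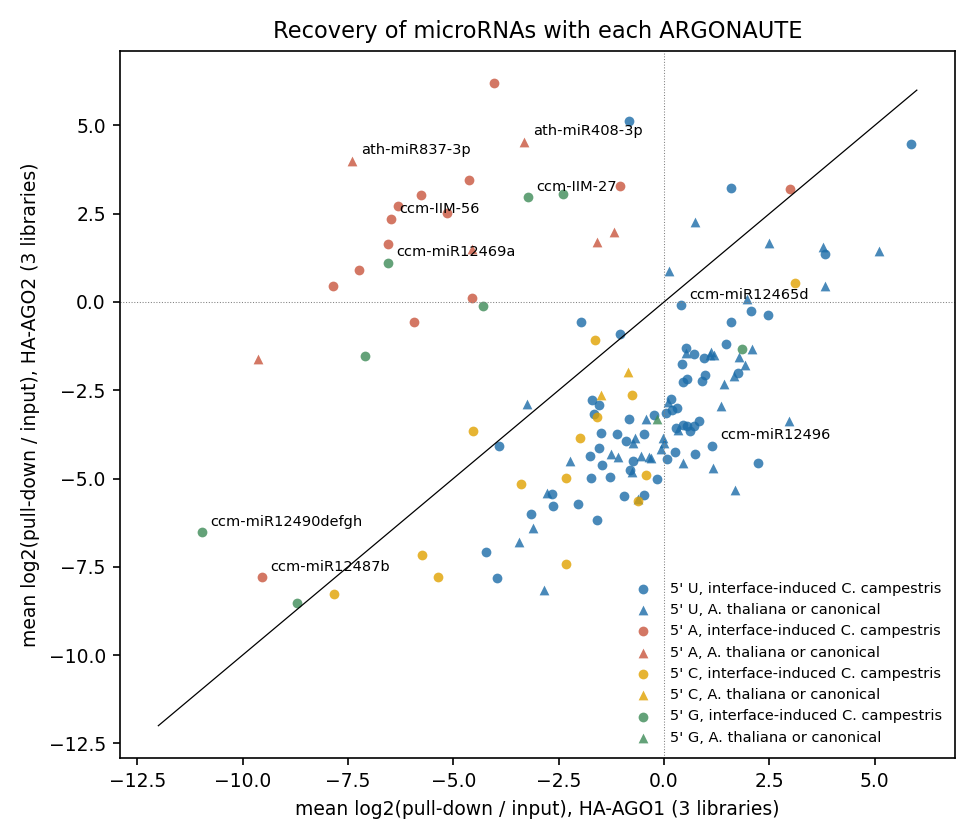
Mean log2 ratio of pull-down over input for each tested microRNA with AGO1 (x axis) and AGO2 (y axis), coloured by 5' nucleotide; circles are interface-induced C. campestris microRNAs, triangles those of A. thaliana and canonical ones of either species, and the line marks equal ratios. Most 5' A microRNAs lie above the line (17 of 20 called) and most 5' U microRNAs below it (68 of 104 called).

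By group, 5' U microRNAs had 1 higher and 68 lower with AGO2 (1 and 68 adjusted over the list alone), with 38 and 44 lower without AGO2 replicates 3 and 4 (adjusted over the list alone 32 and 40, and 44 without AGO1 replicate 4). Their median was -3.18, and camera called them with either correlation (adjusted p = 0.0138 with an estimated correlation). After centring 0 were higher and 97 lower. 5' A microRNAs had a median of 7.93 (18 higher adjusted over the list alone), with adjusted p = 0.156 with an estimated correlation. After centring their median was 4.24, with 12 higher over all features. Of 98 C. campestris microRNAs 18 were higher and 43 lower (the same numbers adjusted over the list alone), with adjusted p = 0.11 with an estimated correlation, and 25, 21 and 21 lower without AGO1 replicate 4 and AGO2 replicates 3 and 4. After centring it had 10 higher and 72 lower (12 and 77 adjusted over the list alone). With microRNAs as the only background this list turned to higher (adjusted p = 0.392). Of 38 conserved microRNAs 5 were higher and 25 lower (5 and 27 adjusted over the list alone; 2 and 31 over all features after centring). The 5 were all 5' A, ath-miR408-3p, the shared miR172cd at 3.30 ± 0.88, which turned to -0.40 after centring, and 3 named after their values were seen, ccm-miR169d at 8.01 ± 1.01, the shared miR390, known to act on trans-acting siRNA precursors, at 6.04 ± 1.04, and miR172ab at 3.15 ± 0.87, which turned to -0.55 after centring. After centring miR390 had 2.34 and lost its call in limma (adjusted p = 0.204). The shared miR166 was lower at -2.89 ± 0.95. The shared miR159a had 0.76 ± 0.94, turning to -2.94 after centring, and ath-miR159b-3p 1.51 ± 0.94, turning to -2.18, neither passing before centring. Of 11 Brassicaceae microRNAs 4 were lower (4 adjusted over the list alone; 1 without AGO2 replicate 3; 11 after centring), ath-miR158a-3p at -3.34 ± 1.06, ath-miR161.1 at -3.31 ± 0.99, ath-miR173-5p at -3.81 ± 1.06 and ath-miR163, and adjusted p = 0.0787 with an estimated correlation held for this list and the conserved one. Of 5 trigger microRNAs 3 were lower (3 adjusted over the list alone; 1 without AGO2 replicate 3; 5 after centring), ccm-miR393a at -4.08 ± 1.14, ath-miR393ab at -3.37 ± 1.05 and ath-miR173-5p (adjusted p = 0.11 with an estimated correlation). Of 7 nutrient stress microRNAs 1 was higher, ath-miR408-3p at 7.85 ± 0.99, and 4 lower, ath-miR398a-3p, ath-miR398bc at -3.66 ± 0.98, and, named after their values were seen, ath-miR399bc at -4.95 ± 1.42 and the 5' U ccm-miR408ab at -4.29 ± 1.41 (1 and 4 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation). The last of these lost its call without AGO1 replicate 3 (-3.70) or AGO2 replicate 4 (-3.23).

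The siRNA loci lay on the AGO2 side, with 457 of 720 higher and 5 lower (457 and 5 adjusted over the list alone; 14 and 24 over all features after centring), a median of 4.50 (0.77 after centring) and adjusted p = 0.00431 with an estimated correlation. Without the filter on reads, which favours loci recovered with AGO2, 2128 of 17568 were higher and 12 lower. By class, 20 of 23 21-nt and 93 of 117 22-nt loci were higher (1 and 2 after centring), and the 20 became 13 without AGO1 replicate 4 or AGO2 replicate 3. The list of 24-nt RNAs had 344 higher and 8 lower (339 and 8 adjusted over the list alone, adjusted p = 0.0639 with an estimated correlation; 11 and 28 over all features after centring). Without AGO1 replicate 3 it had 223 higher (202 adjusted over the list alone), and the 8 lower became 5, 4 and 5 without AGO1 replicate 3 and AGO2 replicates 3 and 4. The 5 lower loci became 2 and 1 without AGO1 replicates 2 and 3, and 1 and 3 without AGO2 replicates 3 and 4. Cluster_23950 rose by 4.41 ± 0.98, Cluster_49936 by 4.33 ± 1.01 and Cluster_49941 by 3.80 ± 0.89. Of the 5 lower loci the 24-nt locus Cluster_11791 (chromosome 5, 2914690 to 2915108) had -5.59 ± 1.67 and lost its call without AGO1 replicate 2 (-3.25). The other 4 were named after their values were seen, namely Cluster_52600 at -6.26 ± 2.11, Cluster_38614 at -4.51 ± 1.77, Cluster_28731 at -4.50 ± 1.71, and the 22-nt locus Cluster_22543 (chromosome 9, 5111177 to 5111594) at -4.33 ± 1.64. Each of these 4 lost its call in 3 to 5 of the 6 fits that left out a library, Cluster_28731 falling to -2.81 without AGO1 replicate 3.

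Over all features, 481 were higher and 78 lower with AGO2 in limma, and 27 higher and 139 lower after median centring, which lowered the median difference by 3.75; in 72.4% of features (against 14.2% by chance with the ratios present) the lines did not overlap (73.5% of the 559 with all 6 ratios, against 10% by chance). The 78 lower fell to 42 without AGO2 replicate 3 and 51 without AGO2 replicate 4, and the 73 microRNAs among them to 41, 48 and 49 without AGO2 replicates 3 and 4 and AGO1 replicate 4. Without AGO2 replicate 3 the calls of miR166 (-2.29), ath-miR158a-3p (-2.57), ath-miR161.1 (-2.72), ath-miR173-5p (-2.82) and ath-miR393ab (-2.63) were lost, and that of miR166 also without AGO1 replicate 3 (-2.63) or 4 (-2.36).

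**Figure D4:**
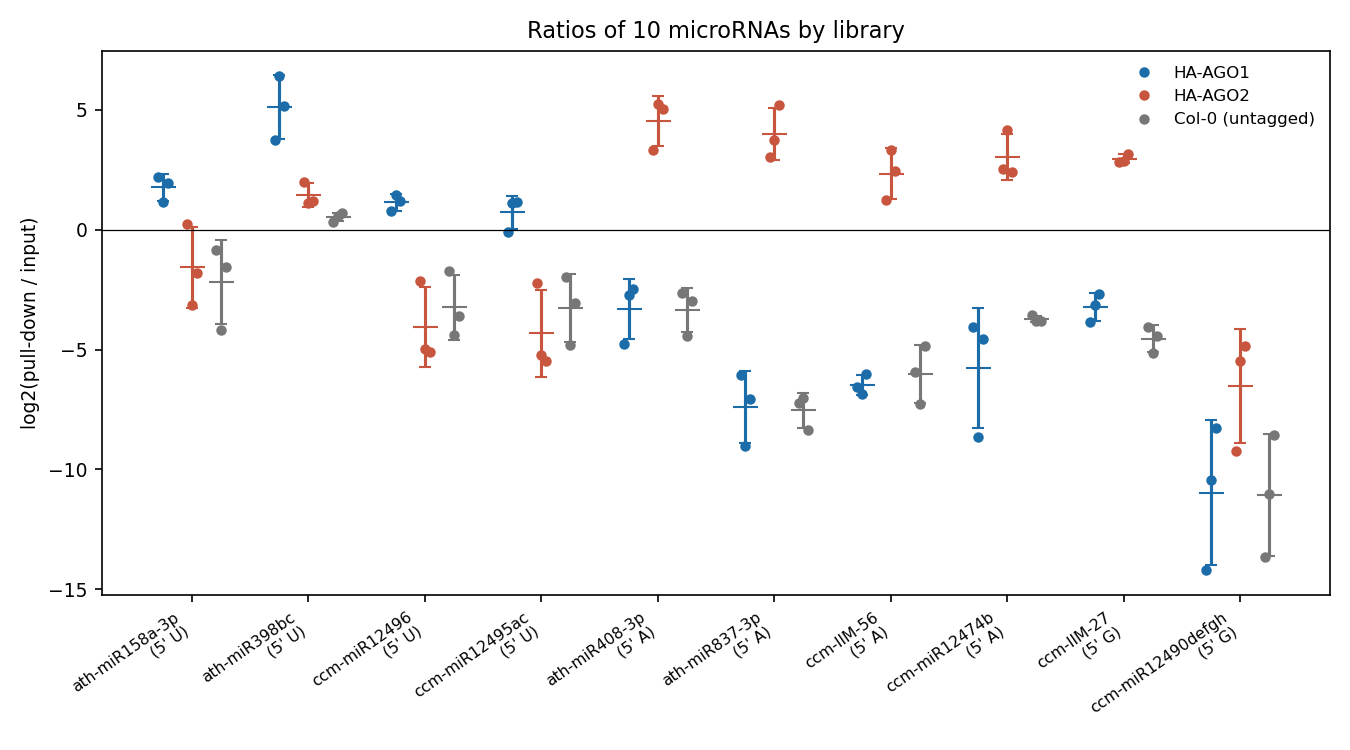
Log2 ratio of pull-down over input (y axis) for 10 microRNAs (x axis) in the AGO1, AGO2 and Col-0 lines; points are libraries and bars show the mean and SD (n = 3). ath-miR398bc has 5.11 with AGO1 and 1.45 with AGO2, whereas ccm-IIM-56 has -6.47 with AGO1 and 2.35 with AGO2.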

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

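The tests of explanations and of other splits in this part were chosen only after the result was seen, unlike the comparison of AGO2 with AGO1 itself. Among microRNAs that do not start with A, 7 were called higher with AGO2 than with AGO1, against the direction of 68 of the 104 5' U microRNAs, and the test was of the difference itself in limma. All 7 were C. campestris microRNAs of 21 nt induced at the interface. The difference was 7.67 ± 1.22 (SE, log2) for ccm-miR12469a (GTTGCTACATTTCAAGCTGGC), 6.18 ± 0.83 for ccm-IIM-27 (GTGAACATCATCCACTACACG), 5.96 ± 1.11 for ccm-miR12481 (TATGTAGCAATTTTGAAGAAT), 5.57 ± 1.26 for ccm-miR12487ac (GAAAACATATTGTTGCTCGAC), 5.48 ± 1.52 for ccm-IIM-102 (GCTTGAAGCTATTGATCCATG), 4.45 ± 1.51 for ccm-miR12490defgh (GTCGCCATTCTTTATTCGTGA) and 4.20 ± 1.72 for ccm-miR12497c (GTACCATGATTTGCACACGAG). All but ccm-miR12481 start with G. Of 8 parasite 5' G microRNAs tested, 6 were higher with AGO2 and 1 lower, ccm-miR12474a at -3.18 ± 1.14. The call of ccm-miR12490defgh was lost without AGO1 replicate 2 (2.82), AGO2 replicate 3 (3.92) or AGO2 replicate 4 (3.61), and its ratio over input was below 0 even with AGO2 (-6.52). The call of ccm-miR12497c was lost without AGO1 replicate 4 (2.21) or AGO2 replicates 2 (3.76), 3 (4.27) or 4 (4.58). After median centring all 7 differences stayed above 0, and 1 of the 7 kept its call, ccm-miR12469a at 3.97 (adjusted p = 0.0306). The others had 2.48 (ccm-IIM-27, adjusted p = 0.0521), 2.26 (ccm-miR12481, 0.134), 1.87 (ccm-miR12487ac, 0.283), 1.78 (ccm-IIM-102, 0.445), 0.75 (ccm-miR12490defgh, 0.849) and 0.10 (ccm-miR12497c, 0.975).

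For these 7 microRNAs, low levels in the AGO2 inputs were set against binding to AGO2. In the pull-down libraries alone, without inputs, all 7 of the 7 were still called higher with AGO2, which argues against low inputs as the cause. Reads shared with a nearly identical 5' A microRNA were argued against for 6 of them, whose nearest listed 5' A sequence lay at least 6 mismatches away. For ccm-miR12487ac, 3 mismatches from the 5' A ccm-miR12487b, the AGO2 ratio exceeded that of its neighbour by at least 5.31 on the log2 scale in every library, so that neighbour's reads are an unlikely source. Binding of these parasite 5' G microRNAs by AGO2 remains as a hypothesis, found and tested on the same data, and annealing to a 5' A strand was not tested.

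The microRNA reads of the untagged pull-down started mostly with U (88.1% ± 4.24, SD, n = 3). Lysate left on the beads is argued against as the source of these microRNA reads. Their 5' U share exceeded that of the library's own input by at least 33.5 percentage points in each library, where the inputs had an SD of 9.92. The 24-nt loci took 46.2% ± 4.15 of the listed reads of this pull-down, and the source of their reads was not tested. Reads from the rest of the sequencing pool are argued against too, since the share exceeded that of the other 17 libraries together (52.2%) by at least 31.4 points. Across 149 microRNAs, which are not independent replicates, the untagged ratios correlated with those of AGO1 at 0.64 to 0.82 and of AGO2 at 0.20 to 0.35, a gap of at least 0.407, which is consistent with AGO1-bound RNA in the untagged pull-down. Whether this was the host's own AGO1 held by the beads or material carried over from tagged AGO1 pull-downs alone stays open, and either may make the difference between AGO1 and Col-0 an underestimate.

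Parasite siRNA loci were recovered more with AGO2 than with AGO1 (457 of 720 higher, against 14 higher and 24 lower after median centring and 2128 of 17568 higher without the filter on reads). Centring used the median of features that were mostly these loci, and removed 3.73 of their median difference of 4.50. The centred counts thus cannot say whether the loci as a whole were recovered more. The filter counts pull-down reads, which favours loci recovered with AGO2. The count without the filter includes many ratios that rest on 0 pull-down reads set at 0.5 read, as given above. Depth was first tested by the share of loci higher after thinning, which is not used here, because the loci tested differed before and after. It was tested again on 124 loci chosen by input reads alone, with all libraries thinned to 1 depth. Their median ratio was higher in the lowest AGO2 library than in the highest AGO1 library by 3.24, with an SD of at most 0.498 within a line, so that depth is argued against. Lysate left on the AGO2 beads was first tested against 5' U microRNAs, where the lowest gap was -0.38, which would not have argued against it. Since some 5' U microRNAs such as ath-miR159b-3p were themselves above their input with AGO2, it was tested again against 5' C microRNAs, the least recovered class, where every locus class stood higher in every library by at least 3.19. That class was picked after the values were seen because it was the lowest, so the choice favoured such a gap. The gap argues only against lysate left evenly over all classes. Lysate left unevenly, binding of parasite siRNAs by host AGO2 and recovery of other complexes together with AGO2 all stay open.

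Other splits of the libraries were too few for a share under 0.05. The 10 splits of 6 libraries included 1 with as many calls, the real one, in each comparison between lines. In limma it gave 40 calls against 0 in the highest other split for AGO1 beyond Col-0, 535 against 1 for AGO2 beyond Col-0, and 559 against 1 for AGO2 against AGO1. If the replicate numbers are taken as pairs for AGO2 beyond Col-0, which the low correlations do not establish, only 4 of the 10 splits part all 3 pairs as the real one does, and the other 6 part 1 pair. Among these 4, limma gave 535 calls against 0 in the highest other, and 529 against 0 with the replicate block. Of 4 patterns of signs of the ratios, 1 gave as many calls for each pull-down over its input, again the real one, with 699 for AGO1, 109 for AGO2 and 791 for Col-0 against 0 in the highest other.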

How the results depend on the processing

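The fallback on log2(RPM + 1), thinning, lines without reads at 3 reads, microRNAs fitted alone and microRNAs as the only background were chosen after the data were seen; the other alternatives were fixed earlier. The cause was not tested for any change given here, except that filters and thinning changed how many features were tested. Median centring took out the shift of the siRNA loci, which were 720 of the 869 tested features, and moved microRNAs with it. A sign changed by centring is thus relative to those loci. Named features stayed on their side of the threshold in 1740 values, which include changes of sign in values called neither before nor after. They were weaker in 276, stronger in 62 and reversed in 21. Library composition moved by less than 1 SD in all 35 values. Leaving out 1 of 3 libraries moves their mean by less than 1 SD whatever the values, so such fits could not have shown a larger move. Setting lines without reads at 3 reads changed no named call or count of calls by over 1.5 times. Of 50 simulated changes of log2 size 3, limma called 18% for AGO1 and 10% for AGO2 beyond Col-0 (37.5% and 17.2% of the 24 and 29 with enough reads to be tested), so that such changes can go uncalled. In the simulation 669 of the 869 features were unchanged and all lines had the Col-0 ratios. In the data 531 were higher with AGO2 beyond Col-0, so the simulated shares do not give the sensitivity of that comparison.

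Counts of calls changed by over 1.5 times as follows. Median centring gave 159 for AGO1 over input (699), 53 for Col-0 over input (791), 0 for AGO1 beyond Col-0 (40, with 121 at an unadjusted p under 0.05 in limma after centring), 120 for AGO2 beyond Col-0 (535) and 166 for AGO2 against AGO1 (559). Without a filter on reads the counts were 15725 (AGO1 over input, of 17757 tested), 2868 (AGO2 over input, 109 before), 16538 (Col-0 over input), 0 (AGO1 beyond Col-0 in limma, with 325 at an unadjusted p under 0.05), 2642 (AGO2 beyond Col-0) and 2205 (AGO2 against AGO1). With a mean of at least 10 RPM they were 182 for AGO1 over input, 257 for Col-0 over input, 93 for AGO1 beyond Col-0, 129 for AGO2 beyond Col-0 and 183 for AGO2 against AGO1. A pseudocount of 10 RPM gave 192 for AGO2 over input, 69 for AGO1 beyond Col-0, 223 for AGO2 beyond Col-0 and 317 for AGO2 against AGO1, and one of 0.1 RPM gave 5 for AGO1 beyond Col-0. Thinned reads gave 308, 387, 75, 276 and 319 for AGO1 and Col-0 over input, AGO1 and AGO2 beyond Col-0 and AGO2 against AGO1. MicroRNAs fitted alone gave 52, 132, 96, 35 and 97 in that order, against 65, 133, 38, 39 and 97 microRNAs among all features, so that only AGO1 beyond Col-0 moved by over 1.5 times there. Pull-downs without inputs gave 69 for AGO1 beyond Col-0, and log2(RPM + 1) gave 72 there and 169 for AGO2 over input. Leaving out single libraries gave 0 to 5 for AGO1 beyond Col-0 in limma (146 and 123 at an unadjusted p under 0.05 where it was 0), and kept the total counts of the other comparisons within 1.5 times.

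For the replicate block, same-numbered deviations correlated at 0.14, -0.05 and -0.08 between AGO1 and AGO2, and at 0.37, 0.38 and -0.04 between AGO1 and Col-0, so pairing was not settled there either. The block gave 74 calls for AGO1 beyond Col-0, with ath-miR161.1 (adjusted p = 0.0302), ath-miR173-5p (0.0376), ccm-miR393a (0.0321), ath-miR393ab (0.0396) and ccm-IIM-12a (0.0396) added among named features, and 494 higher and 86 lower for AGO2 against AGO1. Between AGO2 and Col-0 the block ended the call of Cluster_38407 (adjusted p = 0.054) and changed no other named call.

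Calls of lists were lost as follows, as camera adjusted p. With an estimated correlation these were, for AGO1 beyond Col-0, trigger 0.211, 5' A 0.352, 5' U 0.0813, Brassicaceae, conserved and nutrient stress 0.149 each and C. campestris microRNAs 0.215. For AGO2 beyond Col-0 they were trigger, 5' A, Brassicaceae, conserved and C. campestris microRNAs 0.225 each, 24-nt RNAs 0.284 and 5' U 0.134. For AGO2 against AGO1 they were trigger and C. campestris microRNAs 0.11, 24-nt RNAs 0.0639, 5' A and nutrient stress 0.156, and Brassicaceae and conserved 0.0787. With microRNAs as the only background they were trigger 0.353, Brassicaceae 0.353 and conserved and nutrient stress 0.257 for AGO1 beyond Col-0, trigger and Brassicaceae 0.555 and conserved 0.733 for AGO2 beyond Col-0, and trigger and Brassicaceae 0.392, conserved 0.455 and nutrient stress 0.865 for AGO2 against AGO1. That background reversed C. campestris microRNAs in all 3 comparisons, at adjusted p = 0.257 (lower) for AGO1 and 0.695 (higher) for AGO2 beyond Col-0, and 0.392 (higher) for AGO2 against AGO1.

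Differences called before or after median centring are counted here as reversed where their sign changed, for features named in the same comparison or from a list. It reversed 16 named differences of AGO2 beyond Col-0, to -1.76 for ccm-IIM-3, -1.70 for ccm-miR12465d, -1.55 for ccm-IIM-34a, -1.23, -1.22 and -0.92 for Cluster_23044, Cluster_38407 and Cluster_41871, -0.34 for miR159a, -3.90 for miR166, -3.87 for ath-miR158a-3p, -4.37 for ath-miR161.1, -0.73 for ath-miR161.2, -4.16 for ath-miR393ab, -0.60 for ath-miR395ade, -0.76 for ath-miR395bcf, -3.58 for ath-miR398bc and -4.38 for ccm-IIM-12a. For AGO2 against AGO1 it reversed miR159a (-2.94) and miR172cd (-0.40). Values that were not called either way also changed sign, such as ath-miR472-3p (-3.27) and ccm-IIM-17 (-2.88) beyond Col-0, and ath-miR159b-3p (-2.18) and ccm-miR12487b (-1.95) against AGO1. A pseudocount of 10 RPM reversed ath-miR395ade (-0.44) and ath-miR395bcf (-0.074) for AGO2 beyond Col-0, and pull-downs without inputs reversed ccm-miR12487b (3.91) there. Of named calls, 10 of 31 for AGO2 beyond Col-0 and 8 of 32 for AGO2 against AGO1 were lost in some fit without 1 library, and 17 of 21 for AGO1 beyond Col-0 in every such fit.

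A test with its own size factors, other size factors in a count model, trimmed-mean scaling of lists and shares without structural or organelle RNA were not run, since the values were ratios and those classes were not analysed here.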

Other observations

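The pairs, orders and medians in this part were all chosen after the values were seen. A pair of miR408 sequences offered a contrast within a family that acts on transcripts of copper proteins. The host ath-miR408-3p (ATGCACTGCCTCTTCCCTGGC) and the 5' U ccm-miR408ab (TGCACTGCCTCTTCCCTGGCT) share 20 nt and start 1 nt apart. The host form stood at 4.54 ± 1.04 with AGO2 (SD, log2 over input, n = 3) and -3.31 ± 1.27 with AGO1, from 12245 and 150 pull-down reads. The other stood at -2.95 ± 1.97 with AGO2 and 1.34 ± 1.33 with AGO1, from 30 and 258 reads. In limma the first was higher with AGO2 by 7.85 ± 0.99 (SE, adjusted p = 4.81e-05) and the second lower at -4.29 ± 1.41 (adjusted p = 0.0158), a call that was lost without AGO1 replicate 3 (-3.70) or AGO2 replicate 4 (-3.23). No other pair of tested microRNAs with different first bases overlapped by at least 18 nt at starts 1 to 3 nt apart.

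Just 1 pair of tested microRNAs differed at the first base alone. The shared miR172ab (AGAATCTTGATGATGCTGCAT) and ath-miR172e-3p (GGAATCTTGATGATGCTGCAT) differ by A1G, counted from 1 at the 5' end. The 5' A form was higher with AGO2 than with AGO1 by 3.15 ± 0.87 (SE, log2, adjusted p = 0.00727), which turned to -0.55 after centring. The 5' G form was lower at -3.14 ± 1.05 (adjusted p = 0.0174), and lost its call without AGO1 replicate 4 (-2.87) or AGO2 replicate 2 (-2.62). The 5' G form thus lay on the opposite side from the 6 parasite 5' G microRNAs called toward AGO2, of 8 tested. It lay on the same side as the parasite 5' G ccm-miR12474a, lower in limma at -3.18 ± 1.14 (adjusted p = 0.0237). That call was kept in 2 of the 6 fits that left out a library. The difference between the members of either pair was not tested.

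Among microRNAs of at least 100 RPM in the inputs, 12 had mean log2 ratios under -3 with both proteins. Which microRNAs these are rests on the pull-down being the numerator of the ratio. The most abundant was the 5' G ccm-miR12490defgh, with 14036 ± 6639 RPM over the 9 inputs (SD) and ratios of -10.97 with AGO1 and -6.52 with AGO2. It was followed by the 5' A ccm-miR12487b (5248 RPM, -9.54 and -7.79), the 5' C ccm-IIM-51 (2534 RPM, -7.83 and -8.26), the 5' G ccm-miR12476b (2167 RPM, -8.70 and -8.53) and the 5' C ccm-miR12492a (2131 RPM, -5.37 and -7.78). Shared miR156, which acts on SPL transcripts, was among them at 190 RPM, with -3.10 and -6.39.

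Host and parasite 5' U microRNAs were compared within the pull-downs. The median ratio of 62 parasite 5' U microRNAs minus that of 15 host ones was -0.12 ± 0.68 (SD, n = 3 libraries, from -0.85 to 0.48) with AGO1 and -0.38 ± 0.54 in Col-0. An exact permutation test of AGO1 against Col-0 gave p = 0.8, where 3 libraries against 3 allow no p below 0.1. Among parasite 5' U microRNAs, the median of 32 of 22 nt minus that of 26 of 21 nt was 0.19 ± 0.62 with AGO1 and -0.40 ± 0.22 in Col-0 (exact permutation p = 0.3). Neither p shows that the groups did not differ.

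AGO2 replicate 2 stood apart from the other AGO2 libraries in its 5' U microRNAs. Their median ratio was -1.90 there, against -3.95 and -3.89 in replicates 3 and 4, and their share of microRNA reads was 33.3% against 19.1% and 16.8%. In the AGO2 inputs that share was 41.9% against 50.3% and 47.5%, so the order rests on the pull-down being the numerator.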
